A study of Homo sapiens with 9 samples.

How the data were processed

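Single-cell RNA was measured in 6 libraries of U2OS cells, 1 library for each of 3 CTD lengths and 2 tags. The labels list 9 samples, since each HaloTag library was sequenced in 2 runs, and the deposited files hold 1 matrix per library. Libraries were made with a 3′ single-cell chemistry and sequenced on a NextSeq 500, per the labels' protocols. Reads were converted with bcl2fastq and aligned to GRCh38, per the submitters' processing notes. UMI count matrices were made by the authors with Cell Ranger 6.1.2, per the file headers, and were used as deposited. The kinetic tables deposited by the authors hold, per gene, a mean, a parameter K and a squared coefficient of variation, each with lower and upper limits. They come from a beta-Poisson fit per the file headers. K, in its own unit, was used here as the burst frequency. The version of that fitting tool is not given in the sources used here. Its values were not scaled for depth. Gene names and coordinates were those of the files and of GENCODE v44 on GRCh38.

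Cells with at least 500 genes and at most 20% mitochondrial counts were kept, which removed between 2.01% and 3.03% of barcodes. No doublet caller was run, so droplets with more than 1 cell were not removed before the phase calls and neighbours. The tag sequences in the matrices were left out of library sizes and tests. Counts of kept cells were summed per library. Genes were filtered with filterByExpr, leaving 18069, scaled with trimmed mean of M values (TMM) factors and tested with edgeR 4.0.16 quasi-likelihood fits of tag plus CTD length in R 4.3.3. HaloTag was compared with Dendra2, and 25R, 52R and 70R with each other, at an adjusted p under 0.05 (Benjamini-Hochberg over all genes tested). With 1 library per genotype, the interaction of tag and CTD served as error, with 2 residual degrees of freedom. Each cell of the design is a single library, so cells were never used as replicates. DESeq2 1.42.0 Wald tests of the same design were run beside it. CPM carried a prior count of 2 on the log scale.

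A set of 32 gene lists was fixed before the files were opened, of which 31 had at least 5 measured members, and was tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01. The same test with the correlation estimated from the residuals was run beside it. Members were also adjusted over the list alone. Named genes were, for the tag, up to 10 per direction with the largest change, and otherwise up to 5, among genes past the threshold with a mean of at least 10 CPM and the same direction in every pair. For bursting the same direction in every pair was not asked. A gene named by 2 parts of the rule counted under both. From each called list, 2 to 4 members past a threshold with the largest change in the list's direction were named. Where the text names others, it says so. A few list members are not reported by name, though they count in their lists.

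Burst frequency and burst size, the mean divided by the frequency, were tested on the log10 scale with limma for 21778 genes with finite values in all libraries, and for 4290 genes with a mean of at least 0.5 UMIs per cell. Each gene's variance was moderated toward a trend over genes. In the 4290 genes, before centring, that prior had 12.66 degrees of freedom for frequency and infinitely many for size. Values per library were compared between tags with exact permutation tests, adjusted over 7 tests. Phases were called from list scores after thinning each cell to 5000 UMIs, with 50 control genes per list member and 25 expression bins. Neighbours were found among 2000 cells per library in 30 principal components of 2000 variable genes, chosen with scanpy 1.11.5. Pairs of libraries were compared on CPM with a pseudocount of 1. Gene lengths came from the annotation. Other tools were anndata 0.12.19, scikit-learn 1.9.0, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 in Python 3.11.15.

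The tests were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. With gene dispersions drawn around the fitted trend with the fitted spread, edgeR recovered 4% and 64% of them between tags, with 3 false calls among 71, and 0% of both between 70R and 25R. DESeq2 recovered 43% and 93% between tags, but 47.5% of its calls were false. With dispersions on the trend itself, edgeR recovered 58% and 96% between tags and 38% and 92% between 70R and 25R, and DESeq2 62% and 96% between tags with 9.2% of its calls false. Camera at the preset correlation gave a p under 0.05 to 1 of 30 unmoved lists between tags and to 2 of 30 between 70R and 25R, and 0 with the estimated correlation. These camera values are for the fitted spread of dispersions. A list that was moved got an unadjusted camera p of 1.9e-14 and 5.54e-18 in these comparisons at the preset correlation. With the estimated correlation it got only 0.0199 and 0.0102, so that version has little power after adjustment over the lists. Simulated genes were drawn independently of each other, so this does not check the preset correlation for lists whose members vary together. Estimated correlations of the real lists ranged from −0.217 (markers of leukocytes) to 0.584 (NRF2 antioxidant genes). For bursting, limma on genes of at least 0.5 UMIs recovered 92% of 2-fold and 100% of 4-fold changes in frequency between tags, and 53% and 93% in size.

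Alternatives tried were DESeq2 size factors, library totals without a composition factor, no filter, a mean of at least 10 CPM, DESeq2, every barcode, leaving out the 5% of cells with the most UMIs, thinning to the smallest library, leaving out mitochondrial and ribosomal protein genes, tag alone, CTD length as a trend, a 2-fold threshold, and other pseudocounts, neighbour numbers and variable genes. For bursting they were centring, the 0.5 UMI filter, limma without trend and tag alone. Each library was left out in turn. Such fits leave a CTD length with 1 library, which was assumed to vary like the others. Centring combined with the 0.5 UMI filter was added after seeing the data. Reads were not aligned here, so the share of tagged and untagged POLR2A transcripts was not analysed here.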

Results

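Single-cell transcriptomes were collected from U2OS cells, a human osteosarcoma line, whose largest RNA polymerase II subunit, RPB1, carried a protein tag at its N-terminus. The tag was HaloTag, an enzyme that binds a synthetic ligand covalently, or Dendra2, a photoconvertible fluorescent protein. Each tagged RPB1 had a C-terminal domain (CTD), the repeat-rich tail that recruits RNA-processing factors, of 25, 52 or 70 repeats (25R, 52R and 70R), of which 52 is the human wild-type number. All cells had received α-amanitin, an inhibitor of RNA polymerase II, at 1 µg per ml for 6 days. Transcripts were counted at their 3′ ends with unique molecular identifiers (UMIs). The 9 samples in the labels were 6 libraries, 1 per genotype, because each of the 3 HaloTag libraries had been sequenced in 2 runs that the deposited counts merge. HaloTag and Dendra2 libraries were sequenced in separate campaigns, so tag and campaign cannot be told apart, while CTD lengths were compared within a campaign. Untagged cells and cells without α-amanitin were not analysed here.

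The HaloTag libraries held 3483, 3705 and 4677 cells at 25R, 52R and 70R with 58.4, 53.9 and 54.3 M UMIs. The Dendra2 libraries held 3121, 2747 and 2718 cells with 52.7, 52.6 and 53.6 M UMIs. The median UMI count per cell was 13466 ± 2605 (SD, n = 3) in HaloTag and 17588 ± 1593 (n = 3) in Dendra2 libraries (two-sided exact permutation test, p = 0.2, where 0.1 is the smallest possible). Median genes per cell were 3801 ± 415 and 4357 ± 285 (n = 3 each, exact p = 0.2). The mitochondrial share of a cell's UMIs was 8.26% ± 1.23 against 5.84% ± 0.39 (n = 3 each, exact p = 0.1, the smallest that 3 against 3 libraries allow, and 0.175 after adjustment over 7 such tests). POLR2A, the gene of RPB1 (GRCh38 chromosome 17, 7484366 to 7514616 in the GENCODE annotation), stood at 192, 307 and 199.9 CPM (edgeR counts scaled to library size) in HaloTag 25R, 52R and 70R and at 311, 244 and 189.6 CPM in the Dendra2 libraries. Its log2 difference between tags was −0.10 ± 0.21 (SE; edgeR adjusted p = 0.829). It was 0.18 without HaloTag 25R and −0.31 without Dendra2 52R. These 3′ counts include any untagged POLR2A transcript, so they do not check which form of RPB1 the cells used.

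The comparison of HaloTag with Dendra2 asked how far the choice of N-terminal tag shapes the transcriptome. Replication-dependent histone transcripts, which package newly made DNA and end in a stem-loop instead of a poly(A) tail, were far lower in HaloTag libraries. HIST1H3D fell by 3.80 ± 0.22 (log2, SE, 6 libraries; edgeR adjusted p = 0.0115), from 79.5, 121 and 74.4 CPM in Dendra2 25R, 52R and 70R to 3.77, 10.8 and 6.42 CPM in HaloTag. HIST2H4B (−3.74 ± 0.33), HIST1H4C (−2.82 ± 0.24), HIST1H3B (−2.78 ± 0.21), HIST1H2BM (−2.80 ± 0.28), HIST1H2BK (−2.79 ± 0.23), HIST1H2AG (−2.46 ± 0.16) and HIST1H2AH (−2.42 ± 0.18) fell too, with adjusted p from 0.0115 to 0.0229. HIST1H2BF, HIST2H2AB, HIST1H4E and the linker histone gene HIST1H1E fell by 2.00 to 2.05 with adjusted p from 0.0179 to 0.0305. Of the 20 measured histones of the list fixed before the data were examined, 14 fell over all genes tested and 17 when adjusted over the list alone. None of the 20 was higher (median log2 −2.01, and −2.46, −1.95 and −1.82 in the 25R, 52R and 70R pairs). The list was lower as a group (camera adjusted p = 2.76e-21; adjusted p = 0.583 with an estimated correlation). One member, H1F0, named after its values were seen, encodes a replacement histone, and its log2 difference was −0.18. Some histone genes are close to each other in sequence, so the split of reads among those may be uncertain, which was not tested.

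**Figure D1:**
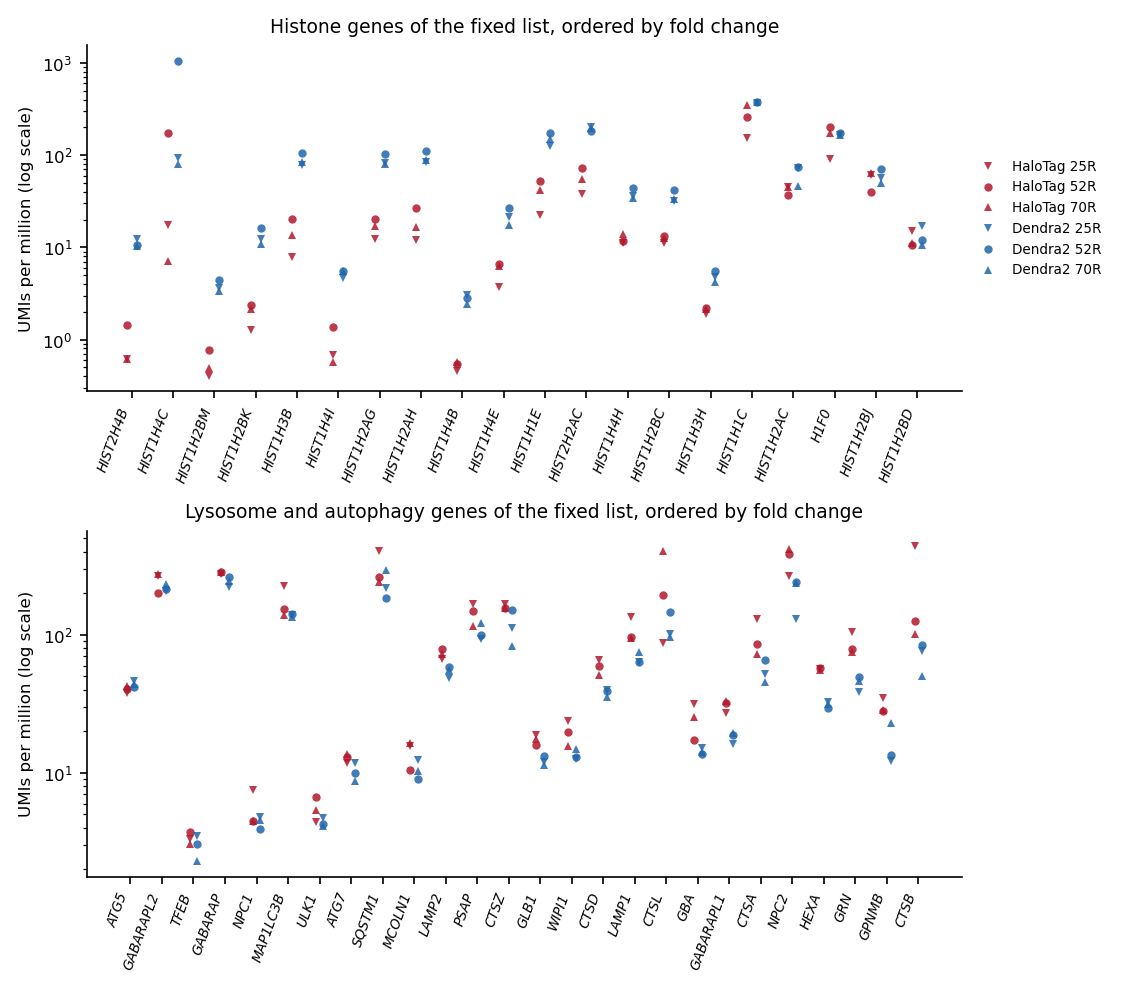
CPM on a log scale of measured histone genes (top) and lysosome and autophagy genes (bottom), ordered by fold change, with 1 marker per library coloured by tag and shaped by CTD length. The whole histone list sums to 507 to 951 CPM in HaloTag and 1448 to 2582 CPM in Dendra2 libraries, and the whole lysosome and autophagy list to 2580 to 3104 and 1739 to 1990 CPM.

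Among genes that rose with HaloTag, TNFRSF11B, the secreted osteoprotegerin that restrains osteoclasts, increased by 2.36 ± 0.21 (log2, SE; edgeR adjusted p = 0.0173). COL6A3, a chain of type VI collagen, rose by 2.09 ± 0.17 (adjusted p = 0.0148) and the matrix protein fibronectin, FN1, by 1.31 ± 0.14 (adjusted p = 0.026). FBXO32, a ubiquitin ligase component induced in muscle atrophy, rose by 2.41 ± 0.27 and TXNIP, an inhibitor of thioredoxin, by 2.13 ± 0.22 (adjusted p = 0.0313 and 0.0257). The long noncoding RNAs MIAT (2.64 ± 0.31) and MANCR (2.20 ± 0.18), and C6orf15 (3.11 ± 0.32), C5orf46 (1.87 ± 0.23), LEMD1 (1.79 ± 0.19) and KLHL24, a ubiquitin ligase adaptor (1.58 ± 0.18), rose as well, with adjusted p from 0.0148 to 0.0448. PLCG2, a phospholipase of receptor signalling on chromosome 16 (81779279 to 81962685), fell by 2.09 ± 0.15 (adjusted p = 0.0131), from 226, 250.2 and 229 CPM to 44, 71.4 and 53.2 CPM. Over 18069 genes, edgeR called 59, with 28 higher and 31 lower, and all 59 had the same direction in the 3 pairs of equal CTD length. That agreement follows largely from the test, whose error is the disagreement between these pairs, and adds no replication. Histone genes made up 26 of the 31 that fell. The other 5 were PLCG2 and, named after their values were seen, TOMM40, PALM3, AL627171.2 and AC093655.1. Of all genes tested, 3546 (19.6%) had an unadjusted edgeR p under 0.05, a background for the counts adjusted over a list alone. DESeq2 called 1130 genes (550 higher, 580 lower), the 59 among them. With library totals in place of composition factors, under which the median log2 of all genes was 0.111 instead of 0.025, edgeR called 98 with 65 higher and 33 lower. The edgeR p-values rest on the spread between single libraries, with 2 residual degrees of freedom, moderated toward the trend over other genes. The labels describe no separate cultures of a genotype. The count was 0 without HaloTag 52R, 0 without Dendra2 70R, 8 without Dendra2 52R and 20 without HaloTag 70R, in fits with 1 residual degree of freedom, and 88 and 80 without HaloTag 25R and Dendra2 25R.

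Lysosome and autophagy genes, the degradative machinery of the cell, were higher in HaloTag libraries for 26 of 27 measured members (median log2 0.52, with 0.74, 0.44 and 0.51 in the 25R, 52R and 70R pairs). None passed over all genes tested and 13 rose when adjusted over the list alone. The largest rises were those of the protease CTSB (1.35 ± 0.41, SE), the glycoprotein GPNMB (0.96 ± 0.24) and the progranulin gene GRN (0.94 ± 0.18). The list was higher as a group (camera adjusted p = 9.02e-10; adjusted p = 0.583 with an estimated correlation). Of 32 measured extracellular matrix and osteoblast genes, 2 rose over all genes tested (COL6A3 and FN1); adjusted over the list alone 7 rose, among them the phosphatase of mineralization ALPL (2.45 ± 0.39) and the protease MMP2 (1.11 ± 0.15). SERPINH1, a collagen chaperone named after its values were seen, fell by 0.54 ± 0.14. Its median was 0.16, with 0.26, −0.04 and 0.57 in the pairs (camera adjusted p = 0.0173; adjusted p = 0.588 with an estimated correlation), and the call was lost without HaloTag 70R (median 0.25, adjusted p = 0.12) and without Dendra2 70R (0.25, adjusted p = 0.126). The median was 0.31 without either 52R library.

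S phase genes had a median log2 of −0.28 in HaloTag against Dendra2 libraries, with 32 of 43 below 0 (camera adjusted p = 3.17e-06; adjusted p = 0.583 with an estimated correlation). Proteasome subunits were lower for 27 of 31 members (median −0.22, adjusted p = 6.86e-06; adjusted p = 0.583 with an estimated correlation) and nuclear-encoded oxidative phosphorylation subunits for 62 of 73 (median −0.20, adjusted p = 2.13e-07; adjusted p = 0.583 with an estimated correlation). None of the members of these 3 lists passed over all genes tested or adjusted over the list alone. Cytosolic ribosomal protein genes had a median of −0.14 and 63 of 79 below 0, with 0 called over all genes tested and 3 when adjusted over the list alone, among them RPL27A and RPL38 (camera adjusted p = 4.24e-05; adjusted p = 0.61 with an estimated correlation). Splicing factors had a median of −0.15 with 38 of 49 below 0, and 9 fell when adjusted over the list alone, among them SRSF3 (−0.62 ± 0.12, SE) and SNRPF (−0.61 ± 0.14), against 0 over all genes tested (camera adjusted p = 6.86e-06; adjusted p = 0.583 with an estimated correlation). Their median was −0.24 without HaloTag 70R or Dendra2 70R. G2/M phase genes had a median of −0.15 (42 of 54 below 0, 0 members called either way; camera adjusted p = 0.000119; adjusted p = 0.588 with an estimated correlation), and the median was −0.09 without HaloTag 25R, −0.10 without Dendra2 25R and −0.23 without either 70R library. Genes of at least 10 CPM were also split into 5 groups by genomic length. Their median log2 between tags rose from −0.149 in the shortest group (median 5.55 kb) to 0.05 in the longest (155.66 kb). Camera took no account of length or level, so small list shifts between tags were not told apart from this drift. The lengths of the list members were not compared.

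The remaining lists that passed the camera test lost their calls in some fits with 1 library left out. Cholesterol biosynthesis genes were lower for 22 of 24 members (median log2 −0.38, camera adjusted p = 1.08e-05; adjusted p = 0.61 with an estimated correlation), with −0.23, −0.002 and −0.72 in the 25R, 52R and 70R pairs, and the median was −0.12 without either 70R library (adjusted p = 0.0508 without HaloTag 70R). NRF2 antioxidant genes (median −0.22, adjusted p = 0.00162; adjusted p = 0.671 with an estimated correlation) lost the call without HaloTag 70R (median −0.09, adjusted p = 0.248) and without Dendra2 70R (−0.09, adjusted p = 0.247), and stood at −0.50 without either 25R library. ATF4 targets (median −0.18, adjusted p = 0.0108; adjusted p = 0.671 with an estimated correlation) lost it without either 52R or either 70R library (medians from −0.13 to −0.06, adjusted p from 0.214 to 0.255), and stood at −0.39 without HaloTag 25R and −0.38 without Dendra2 25R. Heat shock genes (median −0.15, adjusted p = 0.00959; adjusted p = 0.588 with an estimated correlation) lost it without HaloTag 70R (median −0.09, adjusted p = 0.0864) and without Dendra2 70R (−0.09, adjusted p = 0.0751). HSPE1 (−0.76 ± 0.16, SE) and 3 more of the 20 heat shock genes fell when adjusted over the list alone, and 0 over all genes tested. RNA polymerase II subunit genes had a median of −0.25 with 9 of 12 below 0 (camera adjusted p = 0.0281, and 0.583 with an estimated correlation). They lost the call without HaloTag 52R, HaloTag 70R or Dendra2 70R, though the medians stayed between −0.37 and −0.17 over all fits with a library left out. The cholesterol, NRF2, ATF4 and polymerase lists had 0 members called over all genes tested and 0 when adjusted over the list alone. Mitochondrially encoded mRNAs were not called (median 0.14, camera adjusted p = 0.165; adjusted p = 0.764 with an estimated correlation). Still, 6 of 13 rose when adjusted over the list alone, led by MT-CYB (0.71 ± 0.17) and MT-ATP6 (0.67 ± 0.18), against 0 over all genes tested, beside the mitochondrial share of 8.26% against 5.84%. Of 31 lists tested, 14 were called and 17 were not. The latter included the Mediator complex (median −0.08, adjusted p = 0.126), CTD kinases and elongation factors (−0.13, adjusted p = 0.126), cleavage and polyadenylation factors (−0.06, adjusted p = 0.45), p53 targets (0.06, adjusted p = 0.717) and markers of epithelial cells (−0.19, adjusted p = 0.455) and leukocytes (−0.27, adjusted p = 0.882).

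**Figure D2:**
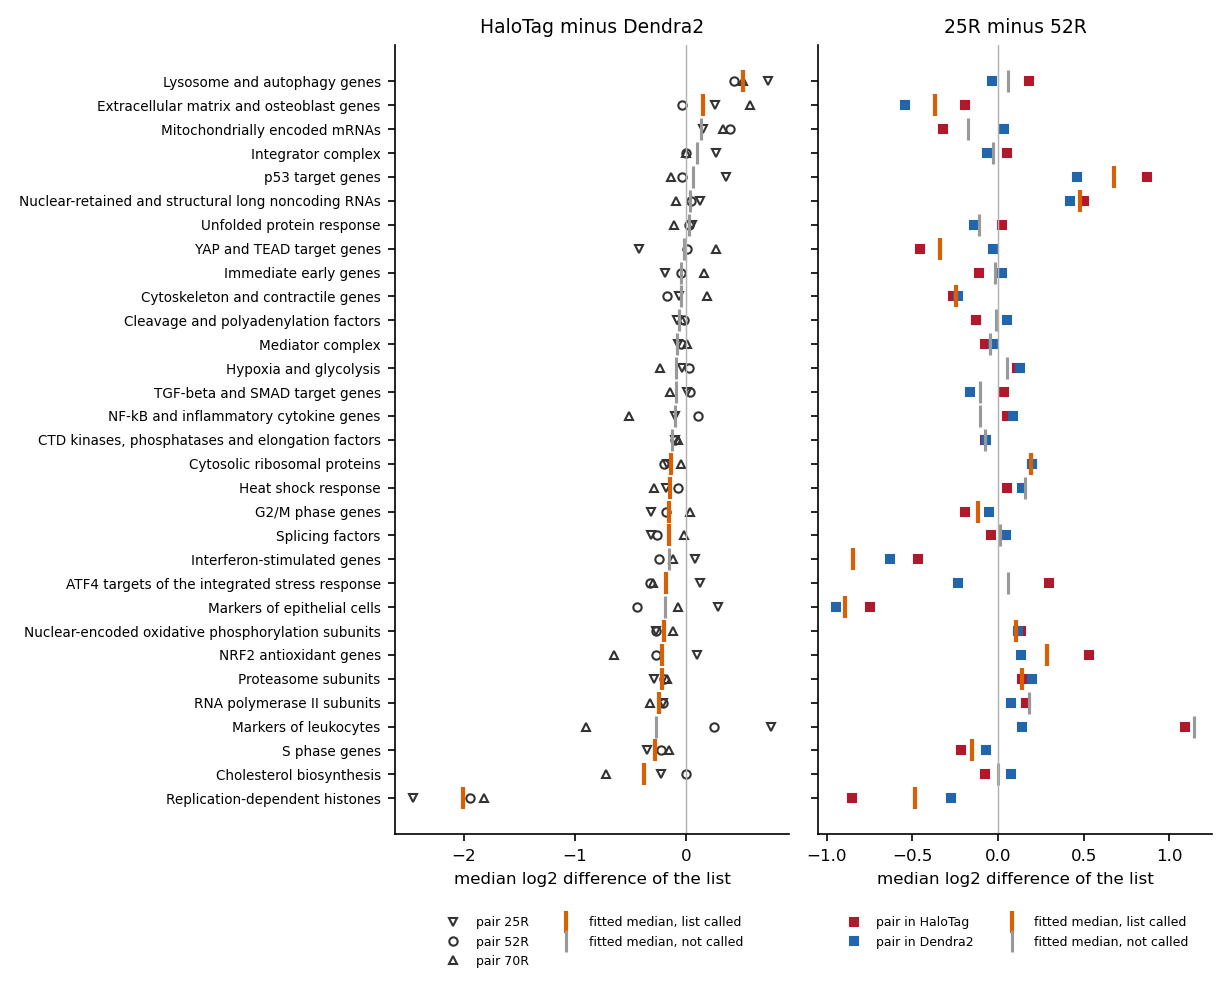
Median log2 difference of each tested gene list between HaloTag and Dendra2 (left, with 1 marker per pair of equal CTD length) and between 25R and 52R (right, with 1 marker per tag); bars are the fitted medians, orange where camera called the list at its preset correlation. Replication-dependent histones lie near −2 in each tag pair, and p53 targets lie at 0.87 in HaloTag and 0.46 in Dendra2 between 25R and 52R.

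Cell cycle phase was called per cell from the S and G2/M lists after thinning to 5000 UMIs. S phase calls made up 29.5%, 31.3% and 28.0% of cells in HaloTag 25R, 52R and 70R, against 44.5%, 46.4% and 40.9% in Dendra2. The means were 29.6% ± 1.68 and 43.95% ± 2.81 (SD, n = 3 each; two-sided exact permutation test, p = 0.1, the smallest possible, adjusted p = 0.175). G2/M calls made up 27.99% ± 0.54 and 32.5% ± 0.75 (exact p = 0.1, adjusted p = 0.175). Without thinning the means were 29.6% and 44.1% for S and 28.9% and 34.6% for G2/M. Thinning left out 50, 61 and 217 shallower HaloTag cells and 101, 34 and 56 Dendra2 cells. Between 23.6% and 31.1% of cells in HaloTag libraries and between 36.7% and 41.1% in Dendra2 libraries had a score within 0.05 of the boundary. Median S scores lay just on either side of 0, from −0.0574 to −0.0316 in HaloTag and from 0.009 to 0.0427 in Dendra2. Free RNA in droplets enters such calls, so they are a range of scores and not a count of dividing cells.

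**Figure D3:**
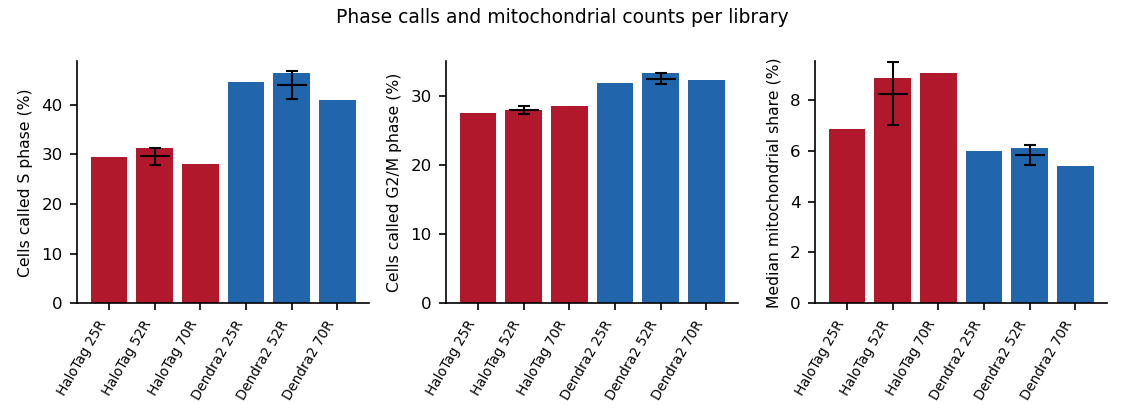
Share of cells called in S and in G2/M phase after thinning, and median mitochondrial share, in percent, with 1 bar per library and the mean and SD of each tag. S phase calls lie between 28.0% and 31.3% in HaloTag and between 40.9% and 46.4% in Dendra2 libraries.

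The comparison of 25R with 52R asked what a CTD of about the yeast length changes against the wild-type length. CD70, a ligand of the tumour necrosis factor family, rose by 1.72 ± 0.15 (log2, SE, 2 libraries each; edgeR adjusted p = 0.0328), standing at 275 and 85.2 CPM in HaloTag 25R and 52R and at 150.5 and 44.6 CPM in Dendra2. The noncoding RNA MANCR rose by 3.05 ± 0.23. NES, the intermediate filament nestin, fell by 2.67 ± 0.18, UNC13D, a regulator of granule release, by 2.41 ± 0.20 and the noncoding RNA LINC01436 also fell (−2.74 ± 0.22), each with the same adjusted p. HIST1H4C, a histone H4 gene on chromosome 6 (26103933 to 26104337), fell by 3.41 ± 0.29, from 176 to 17.4 CPM in HaloTag and from 1043 to 92.7 CPM in Dendra2. Together with AL713998.1 and NUP50-DT, which rose and are named after their values were seen, these were the 8 genes edgeR called (4 higher, 4 lower), with the same direction in both tags. Here too the test favours such agreement, since disagreement between the tags is part of its error. AL713998.1 stood at 56.2 CPM in HaloTag 25R and at most 1.05 CPM elsewhere. Of all genes tested, 2300 (12.7%) had an unadjusted edgeR p under 0.05, again a background for the counts adjusted over a list alone. DESeq2 called 489 (181 higher, 308 lower), the 8 among them. The count moved with every library: 17, 0 and 37 without HaloTag 25R, 52R and 70R and 464, 1 and 31 without Dendra2 25R, 52R and 70R.

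p53 target genes, which arrest the cell cycle or promote cell death after damage, were higher at 25R for 25 of 27 measured members, with a median log2 of 0.68, 0.87 in HaloTag and 0.46 in Dendra2. None passed over all genes tested, and 16 rose when adjusted over the list alone. They included the death receptor FAS (1.22 ± 0.24, SE), the kinase PLK3 (1.10 ± 0.34), ZMAT3, a regulator of RNA decay (0.90 ± 0.21), and the p53 antagonist MDM2 (0.88 ± 0.26). The cell cycle inhibitor CDKN1A (0.82 ± 0.21), named after its values were seen, rose too. The list was called by camera (adjusted p = 1.16e-10; adjusted p = 0.764 with an estimated correlation), and its median was 0.43 without HaloTag 25R. Noncoding RNAs of the structural and nuclear-retained list had a median of 0.48; 7 of 18 rose when adjusted over the list alone and 0 over all genes tested. These were host genes of small nucleolar RNAs such as SNHG5 (0.88 ± 0.20) and SNHG15 (0.75 ± 0.21), and the transcript EPB41L4A-AS1 (0.72 ± 0.20). The list was called (camera adjusted p = 9.67e-05; adjusted p = 0.764 with an estimated correlation). Cytosolic ribosomal protein genes were higher for 69 of 79 members (median 0.19, 0 called either way, camera adjusted p = 5.33e-06; adjusted p = 0.764 with an estimated correlation).

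**Figure D4:**
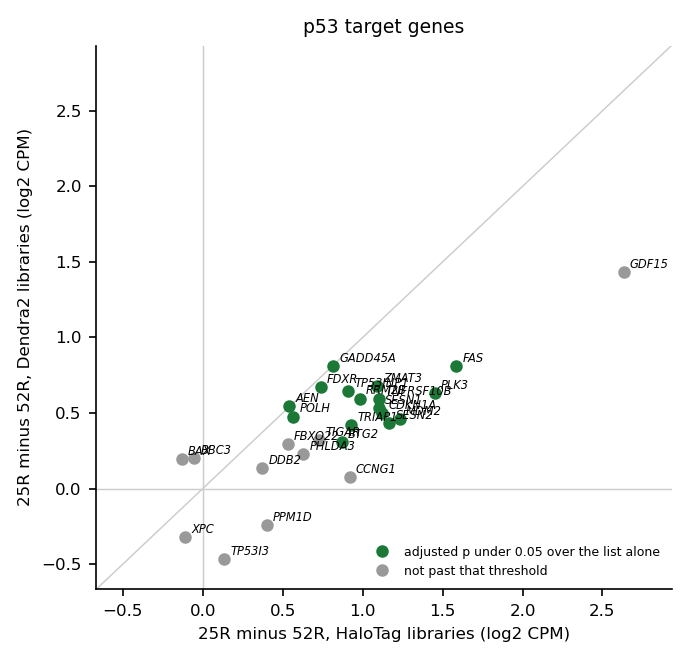
Log2 difference between 25R and 52R for each measured p53 target gene, in the HaloTag libraries (horizontal axis) and in the Dendra2 libraries (vertical axis), with 1 point per gene, green where called over the list alone. FAS lies at 1.59 in HaloTag and 0.81 in Dendra2, and CDKN1A at 1.12 and 0.50.

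Interferon-stimulated genes, the antiviral programme, were lower at 25R for 23 of 28 members (median log2 −0.84 in the fit, and −0.47 and −0.63 in the HaloTag and Dendra2 pairs). Adjusted over the list alone 7 fell, with the largest changes in OASL (−2.49 ± 0.41, SE), MX2 (−2.14 ± 0.46) and ISG20 (−1.50 ± 0.30), against 0 over all genes tested. The peptide transporter TAP1, named after its values were seen, rose by 0.63 ± 0.19. OASL and MX2 averaged 1.09 and 0.415 CPM. The list was called by camera (adjusted p = 1.04e-06; adjusted p = 0.764 with an estimated correlation), with a median of −0.54 without Dendra2 25R and −0.52 without Dendra2 52R. Replication-dependent histones had a median of −0.48 with HIST1H4C called over all genes tested and 4 members adjusted over the list alone (camera adjusted p = 0.000135; adjusted p = 0.764 with an estimated correlation); the median was −0.18 without HaloTag 25R and −0.79 without Dendra2 25R. Extracellular matrix genes (median −0.37, adjusted p = 0.00373), cytoskeleton genes (−0.25, adjusted p = 0.00188), YAP and TEAD targets (−0.34, adjusted p = 0.0234), S phase genes (−0.15, adjusted p = 0.00316), G2/M genes (−0.12, adjusted p = 0.0414) and markers of epithelial cells (−0.89, adjusted p = 0.00469) were lower as lists, and each had an adjusted p = 0.764 with an estimated correlation. In them 0 members passed over all genes tested and 1 when adjusted over the list alone, the tubulin gene TUBA1A (−1.08 ± 0.18). Proteasome (0.14, adjusted p = 0.0183), oxidative phosphorylation (0.11, adjusted p = 0.0128) and NRF2 genes (0.28, adjusted p = 0.0176) were higher as lists, again with an adjusted p = 0.764 with an estimated correlation, and AKR1C1 (2.34 ± 0.47) was their only member called when adjusted over the list alone, against 0 over all genes tested.

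These 9 smaller list calls were each lost in some fit with 1 library left out, which need not mean a smaller shift. Over those fits the medians ranged from −0.95 to −0.57 for epithelial markers and from −0.23 to −0.04 for G2/M genes. They ranged from 0.095 to 0.195 for proteasome and from 0.07 to 0.18 for oxidative phosphorylation genes. Without HaloTag 25R the NRF2 median was −0.0002 (adjusted p = 0.586), and the YAP (median −0.02, adjusted p = 0.871), S phase (−0.08, adjusted p = 0.106) and G2/M (−0.04, adjusted p = 0.729) calls were lost. Without Dendra2 25R the calls of epithelial markers, proteasome and oxidative phosphorylation genes were lost, with medians within the ranges above. The YAP, G2/M and NRF2 medians were then −0.52, −0.23 and 0.75. Without Dendra2 52R the cytoskeleton (−0.16, adjusted p = 0.101), matrix (−0.15, adjusted p = 0.0546), G2/M (adjusted p = 0.0851) and proteasome (0.115) calls were lost, and the epithelial and oxidative phosphorylation medians were −0.57 and 0.18. Without HaloTag 52R the YAP (−0.13, adjusted p = 0.235), G2/M (adjusted p = 0.12) and oxidative phosphorylation (0.07, adjusted p = 0.312) calls were lost.

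The comparison of 70R with 52R asked the same of a lengthened CTD, against the same 52R libraries. HIST1H4C stood lower by 4.10 ± 0.31 (log2, SE), at 7.19 CPM in HaloTag 70R and 81.1 CPM in Dendra2 70R, yet missed the threshold over all genes tested (edgeR adjusted p = 0.103) and passed only when adjusted over the list alone. KLF2, a transcription factor of the immediate early list, stood higher by 1.19 ± 0.17, also passing only when adjusted over the list alone (1 of 24 members, against 0 over all genes tested). The immediate early list had a median of 0.36, 0.42 in HaloTag and 0.10 in Dendra2 (camera adjusted p = 0.000392; adjusted p = 0.923 with an estimated correlation), and its call was lost without HaloTag 70R (median 0.08, adjusted p = 0.456). The median was 0.22 without HaloTag 52R and 0.54 without Dendra2 70R. Interferon-stimulated genes were lower for 23 of 28 members (median −0.26, adjusted p = 0.000392; adjusted p = 0.923 with an estimated correlation), and the median was −0.39 and −0.40 without HaloTag 70R and Dendra2 70R. Histones (median −0.24, adjusted p = 0.000392) and matrix genes (−0.32, adjusted p = 0.0293) were lower, and oxidative phosphorylation (0.12, adjusted p = 0.000392) and proteasome genes (0.13, adjusted p = 0.00652) higher, each with an adjusted p = 0.923 with an estimated correlation. p53 targets had a median of 0.13 (adjusted p = 0.025; adjusted p = 0.929 with an estimated correlation). Apart from HIST1H4C and KLF2, 0 members of these lists passed over all genes tested or adjusted over the list alone.

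For single genes between 70R and 52R, edgeR called 0 of 18069, with 841 at an unadjusted p under 0.05 (4.7%), and DESeq2 called 67 (26 higher, 41 lower). This comparison was not simulated. With as many libraries, 70R against 25R, edgeR recovered 0% of simulated 4-fold changes at the fitted spread of dispersions and 92% on the trend. The 0 thus does not speak against changes. The edgeR count was 2 without Dendra2 70R. Of the 7 list calls, 1 held with each library left out. Without Dendra2 70R the p53 median was −0.06 (adjusted p = 0.98) and the histone (−0.06, adjusted p = 0.25) and matrix (−0.21, adjusted p = 0.521) calls were lost, and the oxidative phosphorylation median was 0.20. Without HaloTag 70R the proteasome (0.075, adjusted p = 0.178) and oxidative phosphorylation (0.06, adjusted p = 0.178) calls were lost and the p53 and histone medians were 0.31 and −0.39. Without HaloTag 52R the oxidative phosphorylation (0.06, adjusted p = 0.11) and p53 (adjusted p = 0.485) calls were lost. Without Dendra2 52R the matrix (−0.11) and proteasome calls were lost, and the p53, histone and oxidative phosphorylation medians were 0.24, −0.37 and 0.19. The proteasome medians stayed between 0.075 and 0.191 over all fits with a library left out. The count of lists was 14 without HaloTag 70R and 12 without Dendra2 70R.

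Between 70R and 25R, the widest difference in CTD length, p53 targets were lower at 70R for 24 of 27 members (median log2 −0.51, −0.69 in HaloTag and −0.18 in Dendra2; camera adjusted p = 6.32e-07; adjusted p = 0.924 with an estimated correlation), with 0 members called either way. Structural and nuclear-retained noncoding RNAs were lower for 16 of 18 members (median −0.51; adjusted p = 3.28e-06; adjusted p = 0.924 with an estimated correlation), and 6 fell when adjusted over the list alone, against 0 over all genes tested, including the small nucleolar RNA hosts SNHG6 (−0.87 ± 0.17, SE), SNHG5 (−0.82 ± 0.20), SNHG12 (−0.78 ± 0.22) and ZFAS1 (−0.74 ± 0.23). Ribosomal protein genes were lower for 69 of 79 members (median −0.22; adjusted p = 3.02e-06; adjusted p = 0.924 with an estimated correlation) and cytoskeleton genes higher for 22 of 32 (median 0.29; adjusted p = 0.000347; adjusted p = 0.924 with an estimated correlation). Interferon-stimulated genes (median 0.26, adjusted p = 0.0204) and YAP and TEAD targets (0.24, adjusted p = 0.0249) were higher and hypoxia and glycolysis genes lower (−0.16, adjusted p = 0.0402), each with an adjusted p = 0.924 with an estimated correlation and 0 members called either way. edgeR called 0 of 18069 genes, with 2212 at an unadjusted p under 0.05 (12.2%), and DESeq2 called 448 (262 higher, 186 lower). On simulated 4-fold changes edgeR recovered 0% with the fitted spread of dispersions and 92% with dispersions on the trend. With the fitted spread, 45.1% of the DESeq2 calls were false. The 0 thus does not speak against changes, and the 448 may hold many false calls. The edgeR count was 6, 1, 493, 1 and 3 without HaloTag 25R, HaloTag 52R, Dendra2 25R, Dendra2 52R and Dendra2 70R. The median was −0.21 for p53 targets and 0.01 for YAP targets (adjusted p = 0.967) without HaloTag 25R, −0.33 and 0.06 (adjusted p = 0.656) without HaloTag 70R. It was 0.36 and 0.37 for YAP targets without Dendra2 25R and Dendra2 70R, 0.19 for cytoskeleton genes without HaloTag 70R and −0.11 for ribosomal protein genes without Dendra2 70R. The interferon call was lost without Dendra2 25R (adjusted p = 0.107) and Dendra2 70R (median 0.41, adjusted p = 0.0824). The hypoxia call was lost without each library but Dendra2 70R (adjusted p from 0.0786 to 0.656), with medians from −0.29 without Dendra2 25R to −0.10 without HaloTag 70R, and −0.26 without Dendra2 70R. The count of lists was 11 without Dendra2 25R.

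The series asks whether the tag changes the transcriptome more than the CTD does. Each tag was its own sequencing campaign, so tag values here hold both, while pairs that differ in CTD length only lie within a campaign. Library pairs that differed in tag only had a median absolute log2 difference per gene of 0.24 ± 0.04 (SD, n = 3 pairs), and pairs that differed in CTD length only had 0.20 ± 0.05 (n = 6 pairs), a ratio of 1.16. Counting noise alone gave about 0.05. The ratio was 1.01 without Dendra2 25R and 1.29 without HaloTag 25R. Between 321 and 993 genes differed at least 2-fold in tag pairs and between 181 and 1263 in CTD pairs, the highest in the pair of HaloTag 25R and 70R. HaloTag 25R stood apart on the first principal component (39.2% of the variance), at −85.4 against 4.9 to 38.2 for the other libraries. The tag accounted for 31% of the variance of the tested genes, the CTD for 43.1% and their interaction for 25.9%, where unrelated values would give 20%, 40% and 40%. Tag differences at different CTD lengths correlated across genes at 0.361 ± 0.124 (Pearson, SD, 3 values) and CTD differences of the 2 tags at 0.256 ± 0.12 (3 values). Genes are not independent replicates, and these correlations have no test. Of a cell's 30 nearest neighbours, 82.8% came from its own library (16.7% under equal mixing) and 95.1% ± 3.56 from its own tag (SD, n = 6 libraries, 50% under equal mixing). Among neighbours from other libraries, 68.5% ± 15.4 shared its tag (40% under equal mixing) and 16.96% ± 13.3 its CTD length (20%).

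Long genes were compared with short ones by genomic length. Across 17985 genes, which are not independent replicates, Spearman's rho with length was 0.06 between tags, −0.05 for 25R against 52R, 0.01 for 70R against 52R and 0.05 for 70R against 25R. Single pairs went both ways, with −0.012, 0.115 and 0.069 between tags at 25R, 52R and 70R. In HaloTag and Dendra2 they were −0.086 and 0.012 for 25R against 52R, −0.007 and 0.021 for 70R against 52R, and 0.063 and −0.002 for 70R against 25R. Among genes of at least 10 CPM the values were 0.223, −0.11, −0.10 and 0.04.

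The authors' kinetic tables give a mean and a parameter K per gene from a beta-Poisson model of the counts. K was taken as the burst frequency, and the mean divided by K as the burst size. In each library, the fitted squared coefficient of variation was within 1% of the inverse of the mean plus the inverse of K, for 100% of genes over 1 UMI per cell. K thus holds all fitted spread between cells beyond counting noise, and differences in depth or phase between cells were not separated from bursting. Among the 4290 genes with a mean of at least 0.5 UMIs per cell, S phase genes had a lower burst frequency in HaloTag libraries, with a median fold of 0.563, and 18 of 27 fell (limma, adjusted p under 0.05). G2/M genes had a median fold of 0.58 and 16 of 49 fell. By gene, the frequency of PBK, a mitotic kinase, was 0.387-fold (adjusted p = 0.00781), of DTL, a ubiquitin ligase subunit of S phase, 0.417-fold (adjusted p = 0.00781), of the kinetochore gene SPC25 0.423-fold (adjusted p = 0.0114), of PLCG2 0.318-fold (adjusted p = 0.000451) and of MAGEA10 0.036-fold (adjusted p = 0.00562). MAGEA10 stood at 0.01149, 0.2089 and 0.5521 in HaloTag 25R, 52R and 70R and at 2.83 to 3.506 in Dendra2 libraries. It was higher for MRPL44, a mitochondrial ribosomal protein gene (2.69-fold, adjusted p = 0.0335), SPTLC1, of sphingolipid synthesis (2.41-fold), STX8, of vesicle fusion (2.40-fold), LINC00511 (2.08-fold) and RNPEP, a peptidase (1.93-fold). Burst size was lower for HIST1H3D (0.08-fold), HIST1H2AG (0.12-fold), HIST1H3B (0.215-fold), MTRNR2L12 (0.252-fold) and MRPL44 (0.258-fold), and for 7 of 10 histones, 34 of 73 oxidative phosphorylation and 8 of 11 NRF2 genes (median folds 0.453, 0.606 and 0.461). It was higher for GNPTG, of lysosomal enzyme targeting (4.21-fold), FN1 (3.52-fold), GTSF1 (3.48-fold), the lysosomal protease CTSB (3.32-fold) and the transcription factor MAF (2.09-fold), with adjusted p from 1.74e-08 to 0.00991. The size of GNPTG was 1.51 in HaloTag 25R and under 0.1 elsewhere, and that of GTSF1 was 0.004844 in Dendra2 25R against 0.297 to 0.4942 elsewhere. In this gene set 132 genes changed in frequency (14 higher, 118 lower) and 462 in size (23 higher, 439 lower). The size p-values took the spread from the trend over genes alone, not from each gene's own libraries. The median size of all its genes was 0.753-fold and the tables are not scaled for depth. After each library was centred on its median, a step chosen after seeing the data, 64 changed in frequency (4 higher, 60 lower) and 139 in size, with 95 higher and 44 lower. S phase genes then had 10 members lower in frequency and 8 higher in size, and G2/M genes 6 and 15. In size, 6 histones, 6 oxidative phosphorylation and 3 NRF2 genes were lower (median folds 0.583, 0.78 and 0.594). The frequency calls of MAGEA10, MRPL44, SPTLC1 and RNPEP (adjusted p = 0.0918, 0.171, 0.0531 and 0.113) and the size calls of GNPTG, GTSF1 and MRPL44 (0.107, 0.219 and 0.168) were lost, at centred folds of 0.036, 2.69, 2.42 and 1.93 in frequency and 5.42, 4.48 and 0.333 in size, of which only the size of MRPL44 was closer to 1 than before.

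**Figure D5:**
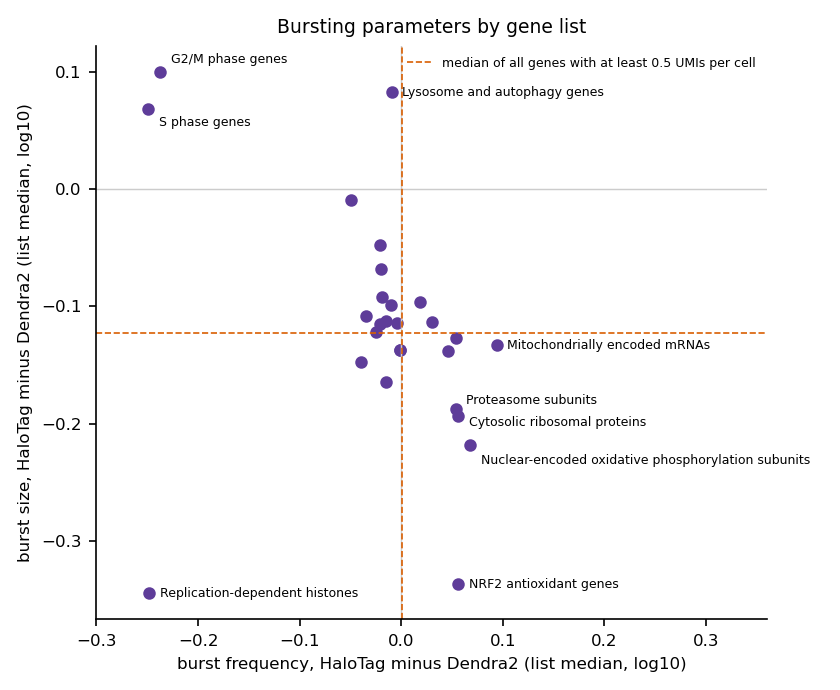
Median log10 difference in burst size against burst frequency between HaloTag and Dendra2 for each list with at least 5 genes of 0.5 UMIs per cell, with 1 point per list; dashed lines mark the medians of all such genes. S phase and G2/M genes lie at −0.249 and −0.237 in frequency, and histones at −0.344 in size.

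In the planned test of all 21778 genes with values, limma called 0 genes for burst frequency in each comparison, with 1203, 1247, 1159 and 1270 at an unadjusted p under 0.05 for the tag, 25R against 52R, 70R against 52R and 70R against 25R, and 0 without limma's trend. For burst size it called 0, 1, 0 and 4 (unadjusted 1629, 860, 674 and 826; 0, 0, 0 and 0 without the trend). On simulated changes that test recovered 0% of 4-fold changes in frequency and 2% in size between tags, so its counts do not speak against changes. The called genes, FRG2C between 25R and 52R and FRG2C, CSF1R, PTCHD1 and AL731537.1 between 70R and 25R, all had under 0.5 UMIs per cell and are named after their values were seen. Burst size counts were 1 to 4, 1 to 28, 1 to 26 and 1 to 28 with a library left out. They were for the tag 4, 1, 1, 3, 3 and 1, for 25R against 52R 28, 26, 1, 15, 15 and 2, for 70R against 52R 6, 26, 8, 1, 17 and 1, and for 70R against 25R 28, 7, 9, 17, 3 and 1 without HaloTag 25R, 52R and 70R and Dendra2 25R, 52R and 70R.

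Between CTD lengths, the set of 4290 genes gave 2, 0 and 1 changed frequencies and 30, 2 and 21 changed sizes for 25R against 52R, 70R against 52R and 70R against 25R, but 0 frequencies and 2, 0 and 0 sizes after centring. Of the genes named here, only TNNT1 kept its call after centring, while the folds of the others moved little, such as 0.154 to 0.171 for TNNC1, 4.321 to 4.004 for KATNBL1 and 0.09 to 0.083 for GTSF1 at 25R against 52R. At 25R against 52R the frequency of the troponin gene TNNC1 was 0.154-fold and of DCTN6, a dynactin subunit, 0.327-fold (limma adjusted p = 0.00829 and 0.00708). The size of KATNBL1 was 4.32-fold, of DCTN6 3.69-fold, of TSR3 3.23-fold, of LINC00520 3.05-fold and of AIG1 2.97-fold. It was lower for GTSF1 at 0.09-fold, through Dendra2 25R (0.004844) against 0.297 to 0.4942 elsewhere, LINC00662 at 0.175-fold, the protease gene CTSL at 0.238-fold, LBH at 0.27-fold and the troponin gene TNNT1 at 0.311-fold. At 70R against 52R the sizes of TSC22D1 and of the keratin gene KRT8 were 0.365-fold and 0.378-fold (limma adjusted p = 0.0456 each). At 70R against 25R the frequency of TMEM9B was 3.53-fold. The sizes of GTSF1 (9.45-fold), LINC00662 (4.58-fold), CTSL (3.31-fold) and the actin-binding CNN1 and TAGLN (2.95-fold and 2.91-fold) were higher, and those of RHOF (0.252-fold), KATNBL1 (0.314-fold), SP110 (0.342-fold), SNHG5 (0.353-fold) and TAF1D (0.365-fold) lower. The tags went opposite ways for 3 of these. GTSF1 size was 0.3396 and 0.297 in HaloTag 25R and 70R, and in Dendra2 25R and 70R CTSL size was 1.178 and 1.162 and KATNBL1 size 1.398 and 2.606.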

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

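The tests of the sequencing campaign, of HaloTag 25R alone, of p53 targets in S phase cells and of the other splits of the libraries were chosen only after the results were seen. YAP and TEAD target genes differed between the tags in the comparison of 70R with 25R, with a median log2 of 0.438 in the HaloTag libraries and −0.039 in the Dendra2 libraries, a difference that was not tested. The matrices also held a signal outside the comparisons, the sequence of the tag itself. HaloTag was read with 535, 699 and 547 UMIs in HaloTag 25R, 52R and 70R, and Dendra2 with 821, 704 and 578 UMIs in the Dendra2 libraries. No group had 4 or more libraries, so the test for a library far from its group was not applied.

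Replication-dependent histones were lower in HaloTag libraries. In cells called S phase their median log2 was −2.166 (95% interval over genes −2.655 to −1.342). This value argues against a smaller share of S phase cells as the whole cause. The intervals here and below are over genes, which are not independent replicates, and hold no spread between libraries. Poorer capture of RNAs without a usual poly(A) tail in the HaloTag campaign might lower them too. Of the 3 other such RNAs chosen, only RMRP was measured well enough, at −0.14, which with 1 gene leaves this open, and replication-independent histones stood at −0.183 (interval −0.491 to −0.026, n = 9). The sequencing campaign stays a candidate explanation for the whole −2.007, because each campaign holds 1 tag.

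Lysosome and autophagy genes were higher in HaloTag libraries. Their median was 0.533 in cells called neither S nor G2/M (95% interval over genes 0.359 to 0.728), which argues against a larger share of G1 cells as the cause. It was 0.571 with cells thinned to the same UMIs (interval 0.424 to 0.857). This argues only against the unequal weight of deep and shallow cells in the summed counts. Thinning keeps the proportions of transcripts within each cell, so it could not show whether shallower cells differ for another reason tied to depth. A starvation-like state with FOXO activity could raise them, and a FOXO list stood at 0.316 with 16 of 19 members positive, 3 of its genes being in other lists too. The interval of the FOXO list, 0.134 to 0.856, reaches below the 0.3 set for a call, so FOXO activity stays open, as do depth per cell and the campaign.

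p53 target genes were higher at 25R than at 52R. In the Dendra2 libraries alone the median was 0.46 with 24 of 27 members positive, against 0.87 in HaloTag. Its 95% interval over genes, 0.227 to 0.596, lies above the 0.2 under which HaloTag 25R alone would have been the cause, but not above the 0.3 set against it, and 1 pair of libraries gives no spread between cultures, so this stays open. The median was 0.709 in cells called S phase (interval 0.438 to 0.891) and 0.79 in cells called G2/M, which argues against a smaller share of dividing cells as the whole cause. In cells called neither it was 0.466 (interval 0.287 to 0.599), which by itself leaves a part of it open. The shares at 25R and 52R were close, though, at 29.5% and 31.3% in S and 27.5% and 27.9% in G2/M in HaloTag. In Dendra2 they were 44.5% and 46.4% in S and 31.9% and 33.4% in G2/M. As far as these phase calls go, such small differences argue against a smaller share of dividing cells as a large part of the rise. A response to the short CTD itself was not told apart from a difference between single cultures.

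The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. With CTD length in the model, 6 of the 9 other splits compare 2 libraries of 1 CTD length, in pairs that give the same counts, so only 3 resemble the split by tag. For genes, the tag gave 59 and the highest other split 1, so 1 split was as large, and the highest of those 3 was 0. For gene lists the tag gave 14 and another split 15, 1 of those 3, so 2 were as large. Over all genes, burst frequency gave 0 and at most 0, and burst size 0 against at most 6, and since any split reaches 0, the 10 as large say nothing. At 0.5 UMIs frequency gave 132 against 16 and size 462 against 9, with 1 as large each, and the highest of those 3 were 0 and 1.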

How the results depend on the processing

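Of the tests in this part, those that join centring and the 0.5 UMI filter were chosen only after the result was seen. No paired analysis was possible because the numbers in the labels mark sequencing runs of 1 library, and each genotype had 1 library. The model itself compared the tags within CTD lengths.

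Of 24 named genes of the tag comparison, 13 kept direction and call under each of the 10 settings with all libraries that tested them (HIST2H4B, HIST1H2BM and HIST1H2BK are not in the set of at least 10 CPM), 11 lost the call with tag alone in the model, and 0 reversed. The log2 changes of these 11 moved little over the settings, such as from 2.61 to 2.92 for MIAT and from −2.90 to −2.60 for HIST1H4C. All 6 named genes of 25R against 52R kept theirs under 9 settings. The number of genes changed between HaloTag and Dendra2 was 98 with library totals without a composition factor, 408 with no filter on low counts, 36 at a mean of at least 10 CPM, 1130 with DESeq2 and 29 with tag alone; the cause was not tested. Without a filter the counts were 106 (25R against 52R), 6 (70R against 52R) and 72 (70R against 25R), and with DESeq2 489, 67 and 448. Leaving out the 5% of cells with the most UMIs gave 1 gene between 70R and 52R; the cause was not tested.

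With the inter-gene correlation estimated, 0 lists were called between tags, 0 between 25R and 52R, 0 between 70R and 52R and 0 between 70R and 25R. DESeq2 size factors and every deposited barcode, the other settings run for lists with all libraries, kept each call.

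With each library left out, gene counts ranged from 0 to 88 between tags, 0 to 464 between 25R and 52R, 0 to 2 between 70R and 52R and 0 to 493 between 70R and 25R. None of the 24 and none of the 6 named genes kept its call in every such fit; these fits have fewer libraries. List counts ranged from 7 to 14 between 70R and 52R and from 6 to 11 between 70R and 25R. Of the called lists, 8 of 14 (tag), 5 of 14, 1 of 7 and 4 of 7 kept their call in all 6 fits. NRF2 genes at 25R against 52R ranged from −0.0002 to 0.7504, p53 targets at 70R against 52R from −0.0621 to 0.3096 and POLR2A between tags from −0.3149 to 0.1805, with reversals; the cause was not tested.

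Burst frequency among genes of at least 0.5 UMIs gave 132 genes between tags, 2 between 25R and 52R and 1 between 70R and 25R, and centring with that filter gave 64 between tags. Tag alone gave 2. Burst size with that filter gave 462, 30, 2 and 21 genes for the tag, 25R against 52R, 70R against 52R and 70R against 25R, and centring with it 139, 2 and 0 for the tag, 25R against 52R and 70R against 25R. Centring alone gave 2 between tags and 2 between 70R and 52R. Without limma's trend the counts were 0 between 25R and 52R and 0 between 70R and 25R, and tag alone gave 1. With each library left out, burst size ranged from 1 to 4 (tag), 1 to 28, 1 to 26 and 1 to 28; the cause was not tested.

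The share of a cell's neighbours with its own tag was 88.07% with 500 variable genes. The correlation of fold change and gene length was, at a mean CPM of at least 10, 0.2226 for fold change and gene length: HaloTag against Dendra2, and −0.10 for fold change and gene length: 70R against 52R. Without a filter, genes with counts of a few UMIs per library entered the test. Depth may limit these low genes most, which was not tested.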

Other observations

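No tests in this part were chosen only after the result was seen. Cells with at least 1 UMI of their tag sequence made up 13.1%, 14.3% and 10.1% of HaloTag 25R, 52R and 70R cells and 20.8%, 20.6% and 15.8% of Dendra2 cells. Transcripts were counted at their 3′ ends, while the tag is N-terminal, so these shares do not measure how many cells expressed tagged RPB1. Such shares also depend on depth, and median UMIs per cell were 13466 in HaloTag and 17588 in Dendra2 libraries. At 9.15, 12.98 and 10.07 CPM in HaloTag and 15.57, 13.4 and 10.78 CPM in Dendra2, the tag sequence was lowest at 70R in Dendra2 and at 25R in HaloTag.

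HIST1H4C, a histone H4 gene, stood at 176 and 1043 CPM in the HaloTag and Dendra2 52R libraries and between 7.19 and 92.7 CPM in the other 4. No other named histone had such a gap. HIST1H3D stood at 10.8 and 121 CPM at 52R against 3.77 to 6.42 and 74.4 to 79.5 CPM. The lower burst frequency of S and G2/M genes in HaloTag libraries stood beside lower shares of cells called in those phases, 29.6% against 43.95% in S.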
